A study of Ligilactobacillus agilis with 10 samples.

How the data were processed

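The data were 10 RNA sequencing libraries of *Ligilactobacillus agilis*, a lactic acid bacterium, grown to the middle of the exponential phase in a basal MRS medium that carried either 1% inulin or 1% glucose. Each carbohydrate had 5 biological replicates, numbered 1, 2, 3, 5 and 6 in both groups. Per the labels' protocols, cells were stabilised, lysed with lysozyme and mutanolysin, and extracted on columns. The RNA was treated with DNase and depleted of ribosomal RNA before stranded libraries were made. The series title names lactose as the second sugar, whereas every sample's own labels and the growth protocol name glucose, and the groups here follow the sample labels.

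Each library came as 1 table of 2005 coding sequences on 25 contigs. Per the file headers, the deposited tables give for each coding sequence a count of total gene reads, a count of unique gene reads and the authors' RPKM (reads scaled to the coding length and to a library total). Total gene reads include reads that match more than 1 gene, and unique gene reads leave them out. One of the tables also holds the authors' difference between the group means and a signed fold, both of a kind other than counts. The difference column equals inulin minus glucose mean RPKM over 8 libraries, 4 per group, with a largest deviation of 2.5e-06 RPKM. Glucose replicate 6 and inulin replicate 3 are the libraries outside those means. Their tables have another layout, with another order of the coding sequences, another style of identifier for 22 of them, RPKM rounded to fewer decimals and a column of deposited log2 values, which equal log2(RPKM + 1) to within 0.0103. The tables were therefore joined by contig, start and end, and all 2005 coding sequences matched in all 10 libraries. The aligner, the counting tool and the genome build are not given in the sources used here, and it is not stated whether counting used the strand.

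Coordinates are those of the deposited tables, with contigs called by the number that ends their names. End minus start is a multiple of 3 for all 2005 coding sequences and is the length behind the RPKM, so 1 of the bounds lies 1 base off the coding sequence, and which bound cannot be told from the values. Coding lengths ran from 81 to 5541 bases with a median of 804. The tables pair no coding sequence with a gene symbol or product. Tests on 29 gene lists fixed before the data were examined, shares of ribosomal and transfer RNA, and the parts of the naming rule that need a gene name were therefore not run, and genes are reported by position.

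The total behind the RPKM was recovered from counts, lengths and RPKM; reads counted in listed genes made up 27.8% to 51.4% of it. Counted reads ranged from 6914783 to 17413330 per library, so 1 read equalled between 0.0574 and 0.145 CPM (counts scaled to library size), and a count of 0 allows up to 0.434 CPM in the shallowest library (3 counts). Sequencing reads without molecular identifiers are not independent molecules, so intervals and this floor cover counting error only. Replicate libraries of a group differed by more than sampling noise in every pair (chi-square per degree of freedom from 28.8 to 752, over genes with at least 10 reads in the pair), and none was treated as a repeat of another.

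Total gene reads were compared between the groups with edgeR 4.0.16 in R 4.3.3: filterByExpr on the group, TMM factors (0.925 to 1.06), the quasi-likelihood F test with group as the only term, and Benjamini-Hochberg adjustment over the 1957 genes tested, with a threshold of 0.05. The 48 genes left out had at most 112 reads summed over all libraries. Fold changes are inulin over glucose. Levels are CPM scaled by the TMM factors, given as mean ± SD over 5 libraries, and shares are percentages of a library's counted reads. A gene was counted as changed at least 2-fold when it passed the threshold with a log2 fold change of at least 1 in size. The standard error of a log2 fold change is its size divided by the square root of F.

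Runs of neighbouring genes were at least 3 tested genes next to each other on a contig and called in the same direction, with strand not used. Their number was set against 1000 permutations of the calls over the tested genes. Measures of whole libraries were compared by two-sided exact permutation tests over all 252 assignments of 5 against 5, adjusted over 5 measures. Single libraries' shares carry 95% Clopper-Pearson intervals. Tests of contigs used camera and fry from limma 3.58.1 on log2 CPM with a prior count of 2.

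The rule for named genes took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with a mean of at least 10 CPM in the higher group and no overlap between the groups, and the 5 genes with the highest mean CPM per group. Its condition on a gene product could not be applied. At most 2 identifiers are printed in each direction. The regions described are the 8 runs of genes changed at least 2-fold with the largest median rise, the 8 with the largest median fall, and the longest run. That choice of regions was made after the data had been seen, because names were lacking.

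Alternatives were other scaling factors, other filters on low counts, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out in turn, and other definitions of a run. Alternatives chosen after seeing the data were the 8 libraries of the authors' difference column, the table layout as a covariate, replicates 1 to 3 or replicates 5 and 6 alone, that split as a covariate, unique gene reads, library size alone, and limma on log2(RPKM + 1) with a mean of at least 1 RPKM.

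The count test was tested on simulated data drawn from the means, library sizes and dispersions of these libraries, for inulin against glucose with 5 libraries each. Of 200 genes given a known change, 199 passed the filter among 1956 genes tested. It recovered 54% of the genes changed 1.5-fold, 90% at 2-fold, 96% at 4-fold and 100% at 8-fold. Of the 177 calls, 8 were false, or 4.52%. Simulated genes varied independently of each other and a smaller part of them changed than was called in the data. Patterns shared by several libraries were not simulated either, so these rates need not hold for the real calls. Exact tests used scipy 1.17.1.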

Results

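*Ligilactobacillus agilis* was grown on inulin, a plant storage polymer of fructose, or on glucose, and its messenger RNA was sequenced at the middle of exponential growth. The question was which genes the bacterium transcribes at another level when a fructan replaces glucose as the added carbohydrate. There were 5 biological replicates per carbohydrate, numbered 1, 2, 3, 5 and 6. Glucose libraries held 13982303, 16569554, 16675519, 6914783 and 12642362 reads counted in the 2005 listed coding sequences, in the order of their numbers. Inulin libraries held 17413330, 16918203, 14660739, 11859524 and 11478707. Counted reads did not differ detectably between the groups (13356904 ± 3991771 on glucose and 14466101 ± 2759330 on inulin, SD, n = 5 each, two-sided exact permutation p = 0.643, adjusted p = 1.0 over 5 measures).

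Reads counted in listed genes made up between 27.8% and 51.4% of the total behind the RPKM, with a 95% counting interval of at most ± 0.0176 percentage points per library. In both groups, replicates 1, 2 and 3 had the higher shares (40.9% to 51.4%) and replicates 5 and 6 the lower ones (27.8% to 36.6%). The means were 40.2 ± 8.44% on glucose and 40.7 ± 8.32% on inulin (SD, n = 5 each, exact permutation p = 0.929, adjusted p = 1.0). Between 1985 and 1997 coding sequences had at least 1 read in a library.

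**Figure D1:**
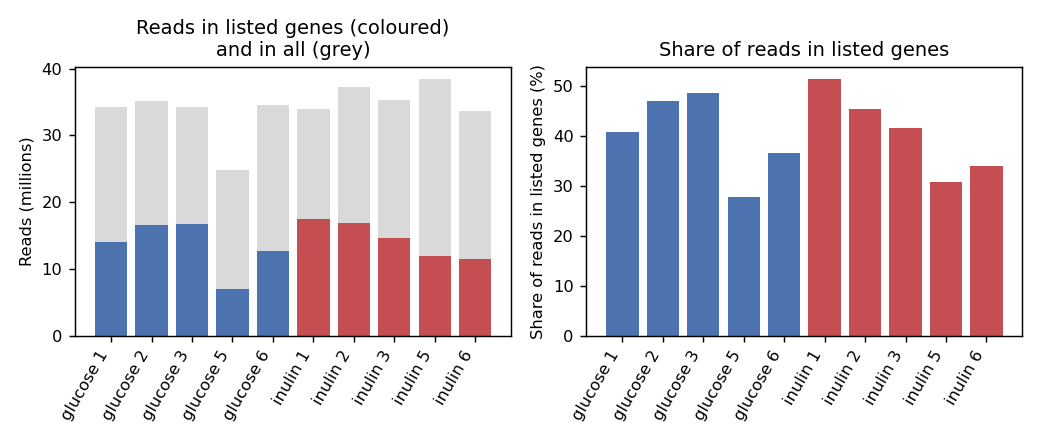
Reads per library (left; coloured bars are reads counted in listed genes, grey bars the total behind the RPKM) and the counted share in percent (right), glucose in blue and inulin in red. Glucose replicate 5 was the shallowest library, at 6914783 counted reads, and replicates 5 and 6 of both groups lay below replicates 1 to 3 in counted share.

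Growth on inulin in place of glucose went with very large rises at a few gene clusters and with falls at others. A cluster of 4 genes on contig 113 rose 480.5-fold in the median, from 0.00462 ± 0.000990% to 2.18 ± 0.184% of all counted reads, and 9 genes of contig 101 rose 70.6-fold, from 0.0345 ± 0.00511% to 2.0 ± 1.44% (SD, n = 5 each). Another 9 genes of contig 101 were 52.7-fold lower on inulin, at 0.0101 ± 0.000974% against 0.479 ± 0.564%, the latter with 1 glucose library well above the rest. Without that library, glucose replicate 5, the median fall was 21.6-fold. A stretch of 20 genes on contig 115 went from 2.96 ± 0.293% to 1.27 ± 0.432%.

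Across the genome, 1026 of the 1957 genes tested passed the threshold in edgeR's quasi-likelihood test, 492 higher and 534 lower on inulin. A change of at least 2-fold was called for 337 genes, 133 of them higher and 204 lower, and 18 genes rose and 23 fell at least 8-fold. Genes called at least 2-fold higher took 4.15 ± 0.510% of counted reads on glucose and 17.0 ± 2.36% on inulin, while those at least 2-fold lower went from 17.8 ± 0.351% to 6.04 ± 1.63% (SD, n = 5 each). In 833 genes, or 42.6% of those tested, the 5 inulin libraries all lay on one side of the 5 glucose libraries, where chance gives 0.794%.

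The calls were unevenly placed along the genome. They formed 127 runs of at least 3 neighbouring genes changed in the same direction, 60 higher and 67 lower on inulin, which held 638 genes or 62.2% of those called. Permuted calls gave 51.1 runs on average and at most 67 (permutation p = 0.001, one-sided, the smallest that 1000 permutations can give). The longest run had 32 genes. Counting only changes of at least 2-fold, there were 35 runs with 184 genes, against 2.46 on average and at most 8 in permuted calls (permutation p = 0.001, the smallest possible).

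Because the libraries split by counted share as well as by carbohydrate, the counts were taken within each part. Replicates 1 to 3 alone gave 1121 called genes, 263 of them at least 2-fold, and replicates 5 and 6 alone gave 763 and 479. At 2-fold, more genes were higher than lower in replicates 1 to 3 alone (139 and 124), the opposite of the balance over all libraries. In the 8 libraries of the authors' own difference column, 954 genes were called and 348 changed at least 2-fold. The authors' deposited table gives a fold of at least 2 for 344 of the genes tested, 120 higher and 224 lower, and none of the 1026 called genes has the other sign there (0 genes). Those folds carry no test and come from 8 of the same libraries, so an equal sign in called genes was nearly fixed in advance.

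The largest rise lay on contig 113 between 9459 and 12073, where the 4 neighbouring genes rose by a median log2 fold change of 8.91. The highest adjusted p among them in edgeR was 4.26e-10. All 10 libraries kept to their group's level, from 0.00351% to 0.00594% on glucose and from 2.01% to 2.47% on inulin. The first gene, identifier 2799475229 at 9459 to 9900, had the largest log2 fold change of any gene the naming rule took, 9.08 with a standard error of 0.18 (edgeR adjusted p = 4.79e-11), and went from 7.45 ± 1.47 to 4082 ± 424 CPM. The gene at 10409 to 11228, identifier 2799475231, rose by 8.93 with a standard error of 0.24 (edgeR adjusted p = 4.26e-10), from 13.4 ± 3.81 to 6561 ± 543 CPM, and by 9.52 in replicates 5 and 6 alone. The remaining members, at 9899 to 10388 and 11239 to 12073, rose by 8.88 and 8.89.

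On contig 101, 9 neighbouring genes between 167511 and 174861 rose by a median of 6.14 on the log2 scale (highest edgeR adjusted p = 0.000352). The inulin libraries differed from each other at this region, with 2.47%, 4.04% and 2.28% in replicates 1, 2 and 3 and 0.687% and 0.544% in replicates 5 and 6 (95% Clopper-Pearson 0.682% to 0.691% and 0.539% to 0.548% for the last 2). In every inulin library the share was above that of each glucose library, the highest of which was 0.0428%. Replicates 5 and 6 alone gave a median rise of 22.2-fold, with all 9 genes called. The region supplied 6 of the 12 largest rises of single genes, between 6.12 and 6.31 on the log2 scale, and its smallest rise was 2.50. These 6 genes had 4.42 to 4.77 in replicates 5 and 6 alone, and the gene at 169695 to 170562, with 6.31 over all libraries, had 5.67 with limma on the authors' RPKM.

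A single long gene on contig 103, at 125165 to 129119 with a coding length of 3954 bases, rose outside any run of 2-fold changes. Its level went from 74.2 ± 9.69 to 5918 ± 2267 CPM (SD, n = 5 each), a log2 fold change of 6.32 with a standard error of 0.32 (edgeR adjusted p = 1.11e-07).

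Of the other rising regions, contig 104 between 153884 and 161454 had 6 genes with a median rise of 3.31 on the log2 scale, and its share went from 0.0333 ± 0.00586% to 0.345 ± 0.215%. One member, at 157275 to 157983, completed the 12 largest rises at 5.14 (standard error 0.46, edgeR adjusted p = 8.77e-06), and had 4.20 in replicates 1 to 3 alone and 6.55 in replicates 5 and 6 alone. On contig 105, the 4 genes between 98145 and 102917 rose by a median of 2.73, from 0.171 ± 0.00843% to 1.13 ± 0.414% of counted reads (highest edgeR adjusted p = 0.000232), and by 4.25-fold rather than 6.64-fold in replicates 5 and 6 alone. Another 4 genes of contig 105, between 121770 and 124733, rose by 2.59 (highest edgeR adjusted p = 0.00876), but only 2 of the 4 kept the groups apart in all libraries, and with limma-voom 2 passed the threshold. At 2 of them, glucose replicate 6 and inulin replicate 3 lay at least 2-fold below, respectively, the median of the other glucose libraries and every other inulin library.

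Smaller rises covered 3 genes of contig 104 between 45683 and 47350 (median 2.05, highest edgeR adjusted p = 0.0210), where the groups overlapped in all but 1 gene and 2 of the 3 genes were called without inulin replicate 2. They also covered 3 genes of contig 101 between 15168 and 16698 (median 1.92) and 7 genes of contig 107 between 99798 and 107356 (median 1.89), with no overlap between the groups in any of these genes. The contig 107 genes went from 0.116 ± 0.0218% to 0.396 ± 0.0501% of counted reads (SD, n = 5 each).

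**Figure D2:**
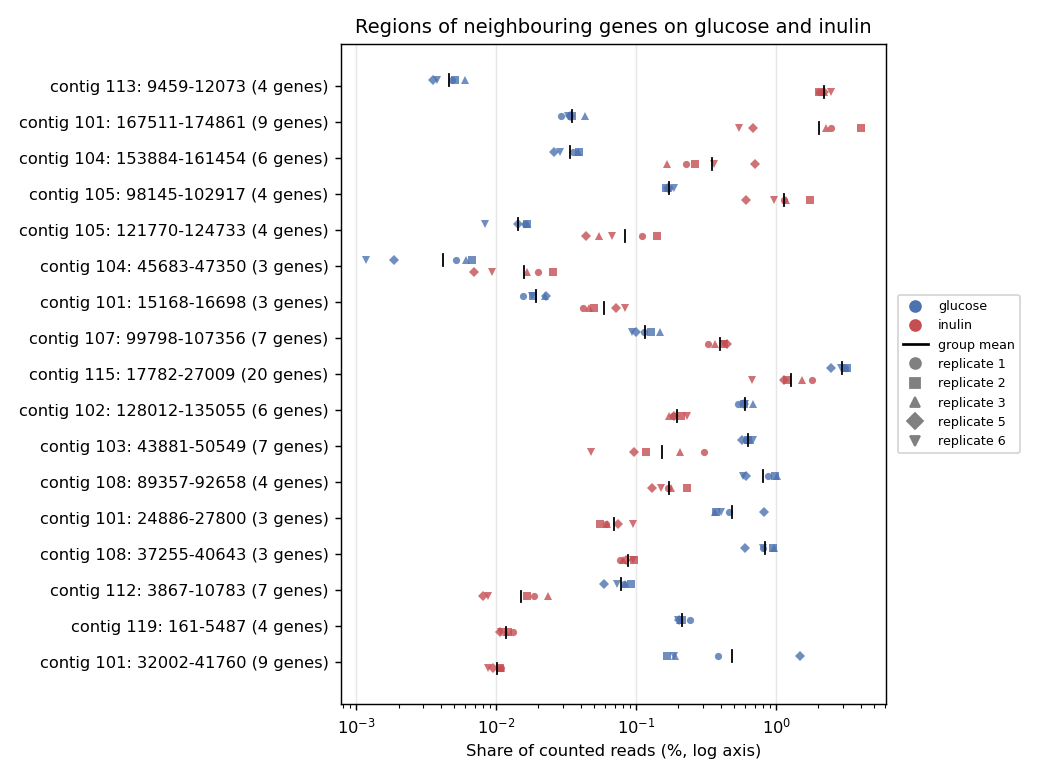
Share of counted reads, in percent on a log axis, of the 17 regions of neighbouring genes named in the text, for each library (symbols by replicate number, glucose in blue and inulin in red) with group means as black bars. The contig 113 region separated the groups most, at 0.00462% and 2.18%, and glucose replicate 5 stood at 1.48% in the contig 101 region from 32002 to 41760.

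The largest fall was also on contig 101, where 9 neighbouring genes between 32002 and 41760 had a median log2 fold change of -5.72 (highest edgeR adjusted p = 0.000614). Glucose replicate 5 held 1.48% (95% Clopper-Pearson 1.47% to 1.49%) against 0.165% to 0.384% in the other glucose libraries, and without it the median fall was 21.6-fold, with all 9 genes still called. In replicates 1 to 3 alone it was 20.9-fold, and in replicates 5 and 6 alone 104.8-fold. The glucose side of the latter is replicate 5 with its 1.48% and replicate 6 with 0.184%, so that value depends on 1 high library. The first gene, identifier 2799473525 at 32002 to 32725, had a log2 fold change of -6.22 with a standard error of 1.02 (edgeR adjusted p = 0.000561), from 435 ± 685 CPM on glucose to 5.77 ± 2.35 CPM on inulin. The next, identifier 2799473526 at 32727 to 32976, had -6.05 with a standard error of 1.00 (edgeR adjusted p = 0.000614). Without glucose replicate 5 these were -4.46 and -4.30. The gene from 40494 to 41760 had the smallest fall of the 9, -4.57, and -3.98 without that library. At lower coordinates of the same contig, 3 genes between 24886 and 27800 had a median of -2.69 and went from 0.482 ± 0.189% to 0.0694 ± 0.0158% of counted reads.

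**Figure D3:**
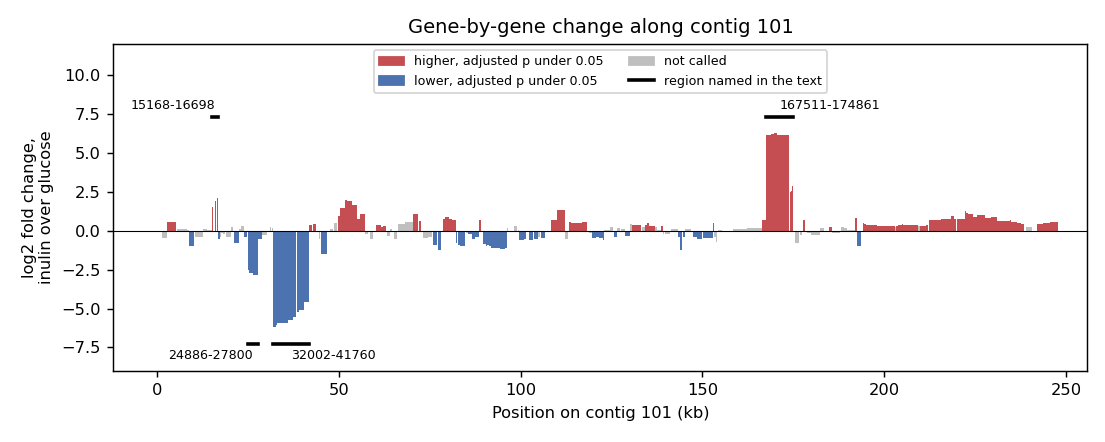
Log2 fold change, inulin over glucose, of each tested gene against its position on contig 101 in kilobases, with bars as wide as the genes and coloured by the edgeR call. The 9 genes from 32002 to 41760 had a median of -5.72 and the 9 genes from 167511 to 174861 one of 6.14.

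Other strong falls were spread over several contigs. On contig 119, 4 genes between 161 and 5487 had a median log2 fold change of -3.79 and went from 0.211 ± 0.0171% to 0.0117 ± 0.00104% of counted reads (highest edgeR adjusted p = 4.46e-07). Among them, the gene at 1021 to 2905 had a log2 fold change of -5.10 with a standard error of 0.15, from 1186 ± 32 to 34.5 ± 6.91 CPM. On contig 112, the 7 genes between 3867 and 10783 had a median of -3.33, and their share went from 0.0776 ± 0.0128% to 0.0151 ± 0.00657%. That fall was 10-fold over all libraries and 15.8-fold in replicates 5 and 6 alone. Single genes on contig 111 at 36165 to 37473 and on contig 106 at 72267 to 73563 had log2 fold changes of -5.18 (standard error 0.57, edgeR adjusted p = 3.40e-05) and -4.37 (standard error 0.52, edgeR adjusted p = 6.15e-05). Without glucose replicate 5 the former was -4.49. In replicates 1 to 3 alone they were -4.27 and -3.54, and in replicates 5 and 6 alone -6.40 and -5.75.

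Contig 108 carried a pair of falling regions. Its 3 genes between 37255 and 40643 went from 0.824 ± 0.148% to 0.0865 ± 0.00923% of counted reads, a median log2 fold change of -3.32, and its 4 genes between 89357 and 92658 went from 0.806 ± 0.202% to 0.171 ± 0.0378%, a median of -2.13 (SD, n = 5 each). The 7 genes of contig 103 between 43881 and 50549 had a median of -1.88 (3.68-fold lower), and 9.72-fold lower in replicates 5 and 6 alone. Those of contig 102 between 128012 and 135055, 6 genes, had a median of -1.54, and the groups did not overlap in any of them.

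The longest stretch of 2-fold changes was 20 genes of contig 115 between 17782 and 27009. Each of the 20 was lower on inulin in all libraries, with log2 fold changes between -1.28 and -1.04 (highest edgeR adjusted p = 0.00469). The median fall was 2.21-fold over all libraries, 1.99-fold without inulin replicate 6 and 1.96-fold in replicates 1 to 3 alone. All 20 genes were still called in both settings, but the median no longer reached 2-fold. Of the 17 regions named, it took the largest mean share of counted reads on glucose.

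The genes with the highest CPM overlapped between the carbohydrates. CPM is not scaled to coding length, so this order is not one of message abundance. On glucose the highest gene was on contig 109 at 73432 to 74620, with 23399 ± 1057 CPM, and on inulin it had 21733 ± 695 CPM (SD, n = 5 each, edgeR adjusted p = 0.205, and 0.0357 when scaled by library size alone). It was the third highest on inulin. The gene with the highest CPM on inulin was on contig 102 at 17718 to 19977, with a coding length of 2259 bases. It rose from 6583 ± 2293 to 29475 ± 6295 CPM, a log2 fold change of 2.16 with a standard error of 0.26 (edgeR adjusted p = 6.21e-05). Next on inulin was the gene of contig 114 at 59977 to 61696, which rose from 12343 ± 1144 to 22043 ± 1611 CPM (edgeR adjusted p = 2.93e-05). The gene of contig 126 at 18 to 912 rose from 9349 ± 946 to 20919 ± 1775 CPM (edgeR adjusted p = 5.18e-06). The gene of contig 102 at 8797 to 9661 was among the 5 highest in both groups, with 18698 ± 1241 and 21603 ± 2759 CPM and no call over all libraries (edgeR adjusted p = 0.110), but was called higher without inulin replicate 5 (adjusted p = 0.0164) and in replicates 1 to 3 alone (adjusted p = 0.0240). Of the others on glucose, the gene of contig 102 at 81460 to 82474 fell from 22805 ± 2155 to 17518 ± 1613 CPM (edgeR adjusted p = 0.00702), a log2 fold change of -0.38. The call ended in replicates 5 and 6 alone (adjusted p = 0.0917) and with limma on the authors' RPKM (adjusted p = 0.252), where the log2 fold change was no smaller, at -0.426 and -0.427. The genes of contig 102 at 77947 to 79273 and of contig 108 at 74420 to 74855 had edgeR adjusted p-values of 0.359 and 0.0648. The latter was called lower without glucose replicate 1 (adjusted p = 0.0405), without inulin replicate 6 (adjusted p = 0.0205), with the split of replicates 1 to 3 against 5 and 6 as a covariate (adjusted p = 0.0316) and when scaled by library size alone (adjusted p = 0.0339).

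The 10 highest genes of each library took 16.7 ± 0.654% of counted reads on glucose and 19.0 ± 0.798% on inulin, with no overlap between the groups (SD, n = 5 each, two-sided exact permutation p = 0.00794, the smallest that 5 against 5 allows, adjusted p = 0.0198). Reads that matched more than 1 gene were rare, at 0.0896 ± 0.0171% on glucose and 0.144 ± 0.0293% on inulin (exact permutation p = 0.00794, adjusted p = 0.0198). None of the genes in the 17 regions shared reads with another gene (0%).

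Libraries of a carbohydrate resembled each other more than those of the other. Pearson correlations of log2 CPM across genes, which are not independent replicates, were at least 0.945 within a group and at most 0.932 between groups. The first principal component held 70.4% of the variance and separated the carbohydrates. The second held 12.3% and set inulin replicates 5 and 6 (-8.82 and -18.9) below inulin replicates 1, 2 and 3 (9.83, 5.78 and 18.3). On glucose it ran from -5.36 in replicate 5 to 6.07 in replicate 6. On the third, which held 7.76%, glucose replicate 6 (-16.5) and inulin replicate 3 (-8.11) had the lowest score of their groups, against at least 0.768 in the other glucose libraries and -6.67 in inulin replicate 6.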

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

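The tests of separate table processing, of sequencing depth and of genomic DNA were chosen after the values at the genes concerned had been seen. The test of reads shared between copies and the other splits of the libraries were chosen before.

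Chance was examined with other splits of the libraries. Of the 126 possible splits of the 10 libraries into 5 and 5, 100 were drawn, and only 1 of them, the real split, gave as many called genes (1026), as many genes changed at least 2-fold (337) and as many runs of neighbours (127). The highest of the other splits gave 0 in each count with edgeR, and at most 525 genes at an unadjusted p under 0.05. A mixed split puts the carbohydrate difference into the spread within its groups, which lowers its calls. With 0 called genes, the 2-fold and run counts are 0 as well and add no support. The splits therefore cannot exclude chance, and show only that no other drawn split gave a call.

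Of 66 groups of 5 values examined, 3 held a library far from the other 4 relative to the range of its group, where chance gives about 1 in 20 groups, or 3.3. The region of contig 105 between 121770 and 124733 took 0.00828% of counted reads in glucose replicate 6 (95% Clopper-Pearson 0.00779% to 0.00880%) and 0.0143% to 0.0165% in the other glucose libraries. The region of contig 101 between 24886 and 27800 took 0.813% in glucose replicate 5 (0.806% to 0.820%) and 0.368% to 0.460% in the others. The gene of contig 114 at 59977 to 61696 had 10406 CPM in glucose replicate 6 (10351 to 10460) and 12340 to 13204 CPM in the others.

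Glucose replicate 6 and inulin replicate 3, whose tables have another layout than the rest, were low at the same genes. In inulin replicate 3, 38 genes lay at least 2-fold below every other inulin library, and 33 of these, or 86.8% (95% Clopper-Pearson 71.9% to 95.6%), were also at least 2-fold below the median of the other glucose libraries in glucose replicate 6. Sequencing depth is argued against by glucose replicate 5, the shallowest library, where 2.63% of the 38 were low (0.0666% to 13.8%), and reads shared between copies by the 2.63% of the 38 with at least 1% shared reads (upper bound 13.8%). A separate alignment or counting of these tables may account for the pattern, a library batch made of the same libraries stays open, and no biological explanation was tested, since the libraries belong to opposite groups. Of the 38 genes, 2 were called between the carbohydrates. Both lie in the contig 105 region from 121770, whose share in glucose replicate 6 is given above.

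In 2 of those 38 genes, both libraries held 0 reads, which allows up to 0.237 CPM in glucose replicate 6 and 0.205 CPM in inulin replicate 3, while the other 8 libraries summed to at least 335 reads for each gene.

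Glucose replicate 5 was high across the contig 101 region from 32002 to 41760, with 1.48% of counted reads (95% Clopper-Pearson 1.47% to 1.49%) against 0.165% to 0.384% in the other glucose libraries. Genomic DNA would have added reads evenly, yet the reads per kilobase at the contig 113 region from 9459 were 0.0106 of those gained here. A difference between cultures within the glucose group may remain, and no biological explanation was tested because the labels name none.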

How the results depend on the processing

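The alternatives that use parts of the libraries, the table layout, unique gene reads, library size alone or RPKM were chosen after seeing the data. The test of rescaled RPKM was stated before its result was seen. No called result changed sign, and in none of the settings did a gene called in both have opposite directions (0 genes). Over the 14 settings within 1.5 times of the 1026 called genes, the count ran from 763 to 1139, and the count of at least 2-fold from 263 to 479 over 15. With each library left out in turn, called genes ran from 910 to 1031, genes changed at least 2-fold from 287 to 361 and runs from 100 to 122. Of 425 values of the 17 regions under alternatives, 422 had all genes of the region called in the same direction. The 3 others were contig 105 from 121770 with limma-voom (2 of 4 called, median 2.33), contig 104 from 45683 without inulin replicate 2 (2 of 3 called) and contig 103 from 43881 with CPM of at least 10 in at least 5 libraries (6 of 7 called). Of 800 single gene values, 791 kept their side of the threshold, as did 51 of 51 library measures.

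Replicates 1 to 3 alone gave 124 genes at least 2-fold lower, and replicates 5 and 6 alone gave 82 runs; the cause was not tested. Runs of at least 5 genes numbered 45 and runs of 2-fold changes 35, by construction fewer. With limma on the authors' RPKM, 529 genes were called, 226 higher and 303 lower, in 57 runs, and all 529 were among the 1026. Rescaling the RPKM to the reads in listed genes gave 1012 called genes, 932 of them shared with the counts, so the share of reads outside the listed genes may account for the lower count. The contig 101 region from 32002 was 30.1-fold lower with limma-voom, 31.1-fold with the replicate block and 27.1-fold on RPKM; the cause was not tested.

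The replicate numbers were not taken as pairs, because the labels do not say that a number marks a shared inoculum. Deviations from the group means correlated at 0.16, 0.11, -0.22, 0.15 and -0.14 between same-numbered libraries. The highest such correlation across the groups was 0.576, between glucose replicate 6 and inulin replicate 3, whose tables have another layout. The next highest was 0.345. Of the 5 glucose libraries, 2 correlated best with their own number. These correlations describe the libraries and do not exclude a shared batch. The replicate block gave 942 called genes, 339 of them at least 2-fold. Replicates 1 to 3 and replicates 5 and 6 nevertheless differed in counted share in both groups, and that split as a covariate gave 1139 called genes. Not run, for lack of gene names or strands, were ribosomal RNA kept or removed, the gene list tests and runs on 1 strand. Depth limits genes with few reads: 48 were not tested.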

Other observations

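The test of contig 115 was chosen after the result had been seen, and the test of neighbouring genes before.

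Several further stretches moved together. On contig 103, 13 genes between 141791 and 151638 went from 0.727 ± 0.0324% to 0.269 ± 0.144% of counted reads (SD, n = 5 each), with a median log2 fold change of -1.36 and no overlap between the groups in any of the 13. On contig 101, 5 genes between 91260 and 96164 went from 1.91 ± 0.159% to 0.832 ± 0.268%, a median of -1.13. The 3 genes of contig 109 between 88282 and 89237 went from 0.547 ± 0.0579% to 0.219 ± 0.0928%. In the other direction, 4 genes of contig 107 between 69735 and 73104 rose from 0.0877 ± 0.00197% to 0.268 ± 0.0292%, and 6 genes of contig 102 between 9808 and 14736 from 0.0145 ± 0.00365% to 0.0470 ± 0.00370%.

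Of the 51 tested genes of contig 115, 42 were called lower on inulin and 4 higher, with a median log2 fold change of -1.04. Camera, which compares a contig's genes with all others, gave an adjusted p of 5.19e-06 over 20 contigs with its preset correlation, and adjusted p = 0.531 with an estimated correlation of 0.548 between the genes. Fry, which does not compare with other genes, gave an adjusted p of 0.00654. It cannot be told apart from these values whether the contig fell as a whole or whether a few jointly transcribed stretches make up the fall, because the estimated correlation leaves too few independent genes. With the preset correlation 6 contigs passed 0.05, and with the estimated correlation none did (0 contigs).

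Neighbouring genes less than 50 bases apart had more similar changes than neighbours at least 200 bases apart. The mean absolute difference of log2 fold change was 0.182 over 861 close pairs and 0.838 over 331 distant pairs (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give). Pearson's r between neighbours was 0.965 for close and 0.280 for distant pairs, across genes, which are not independent replicates. Transcription of close genes as one message is a candidate explanation, and strand was not used.

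Libraries differed in how many genes they alone held low or high. Inulin replicate 6 had 45 genes at least 2-fold below every other inulin library and 13 at least 2-fold above. Glucose replicate 5 had 16 genes at least 2-fold above every other glucose library, and glucose replicates 1, 2 and 3 had 0. Glucose replicate 6 had 41 genes at least 2-fold below every other glucose library and 3 at least 2-fold above.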
